A study of Arabidopsis thaliana with 16 samples.

How the data were processed

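Transcript levels were measured in Arabidopsis thaliana plants, all parts except the roots, on Affymetrix ATH1 arrays, per the labels. The 16 arrays cover 2 genotypes, 2 growth temperatures and 2 sampling times, with 2 arrays in each of the 8 groups. The genotypes are the Landsberg erecta (Ler) wild type and phyB-1, a mutant of the red and far-red photoreceptor phytochrome B. The temperatures are 16 and 22 °C and the times are 4 and 10 h, and the labels do not say from which event the hours were counted. The growth protocol in the labels is worded alike for every sample and gives 11 days at 16 °C followed by 21 days at 22 °C, so the schedule of the plants labelled 16 °C is not clear from it. Nothing in the labels says that the 2 arrays of a group came from separately grown plants, so the p-values below measure the spread between these samples, which can be technical.

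The deposited values are linear intensity values, 1 per probe set, made with MAS5 in GCOS per the submitters' processing notes, which give no versions. RNA was extracted with a column kit and labelled by the manufacturer's one-cycle procedure, per the labels' protocols. The file holds 22810 probe sets, 64 of them array controls, which were left out of the tests. The 2% trimmed means of the deposited intensity values lay within 0.0015% of their median on every array, near 100, so the deposited scaling was kept. The array number, 2 per group, limits the precision of each value.

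Gene names came from the platform annotation table supplied for the probe sets and from the RefSeq gene table of assembly TAIR10.1. Of the 22746 probe sets that are not controls, 13513 had 1 gene in the annotation table, 503 had several and 8730 were not listed there and are unnamed here. Genes were named only from probe sets with 1 gene. PHYB itself, the mutated gene, was among the genes without a named probe set, so its level was not analysed here.

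Values were analysed in R 4.3.3 with limma 3.58.1 as log2(intensity + 16). A fold change on this scale understates the change of dim probe sets. The 13648 probe sets with a mean in the upper 60% were tested, 7374 of them with 1 gene. One mean per group was fitted over all 16 arrays, so that the 8 groups shared 1 estimate of the spread, with limma's moderated test (eBayes with an intensity trend) and Benjamini-Hochberg adjustment. Probe sets with an adjusted p under 0.05 are called. Genotype differences at each temperature and temperature differences in each genotype are means over both times, 4 arrays against 4, and the time difference is a mean over genotypes and temperatures, 8 arrays against 8. The 3 interactions (genotype by temperature, genotype by time, temperature by time) were tested in the same fit.

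The groups share replicate numbers in the labels. The deviations of same-numbered arrays from their group means correlated above 0.1 across probe sets in 27 of 28 pairs of groups, and in all 15 pairs among the 6 groups other than phyB-1 at 16 °C (0.15 to 0.48). The exception was phyB-1 at 16 °C, 4 h against 10 h, at -0.43. The numbers were therefore treated as marking 2 sets of arrays handled together, taken from the labels' replicate numbers, and values within each set are called replicate set 1 and replicate set 2. The sets also differed in dim signal, with lower quartiles of 9.63 to 11.5 in set 1 and 5.84 to 7.63 in set 2.

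The 2 disputed arrays, the array labelled phyB-1 16 °C 4 h replicate 2 and the array labelled phyB-1 16 °C 10 h replicate 2, stood with the arrays of the other time. They kept their labels in the fit of all 16 arrays. An alternative chosen after seeing the data left both out and took the replicate number as a block, and it is called the 14-array fit. In it phyB-1 at 16 °C rests on replicate 1 alone, and the residual degrees of freedom are 5 against 8.

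The rule for named genes was set before the data were examined. It took, for each of 6 comparisons, up to 8 genes with the largest rise and 8 with the largest fall among called probe sets with 1 gene whose arrays did not overlap between the groups within either time (no such condition for time and the interaction), or the 5 genes of smallest p where fewer than 5 passed. To these it added up to 4 called members of each gene list. It also took 12 fixed genes, of which only COR15A had a named probe set. A gene was represented by its named probe set of highest mean. The same rule was applied to the 14-array fit after the data were seen.

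The 22 gene lists set beforehand held 441 genes, of which 70 had a named probe set and 51 were tested. The 8 lists with at least 3 tested genes (shade avoidance, auxin response, flowering time, cold response, photosynthesis, flavonoid and anthocyanin synthesis, cell wall expansion, reference genes) were tested with limma's camera at its preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Another 29 sets were added after the data were seen, namely families sharing a symbol stem with at least 5 tested genes and the chloroplast-encoded genes.

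The fits were tested on simulated data with 200 changed probe sets among 13648, drawn with the residual spread of these arrays. The simulated arrays varied independently, whereas same-numbered arrays here deviated together, so the rates hold for independent arrays only. For the comparison of the genotypes at 22 °C with all 16 arrays, 28 of 50 changes of 1 log2 unit and 48 of 50 changes of 2 log2 units were recovered, with 7 false calls among 138. For the genotype by temperature interaction 17 of 50 changes of 1 log2 unit and 43 of 50 of 2 log2 units were recovered. Alternatives changed the offset (1 and 64), the normalization (quantile, median centring), the filter (none, upper 40%), the variance trend, the replicate block, the array weights, the groups entering a fit and a 2-fold minimum, and left out each array in turn.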

Results

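The arrays compare whole shoots of Ler and phyB-1 plants at 16 and 22 °C, sampled at 4 and 10 h, with 2 arrays per group. The title of the series poses the question whether temperature controls the action of phytochrome B, which the genotype comparisons at each temperature and their interaction address. Median intensities were 30.7 to 41 across the 16 arrays. Within the 6 groups other than phyB-1 at 16 °C, replicate arrays correlated at 0.96 to 0.975 across probe sets.

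The 2 replicate arrays of phyB-1 at 16 °C correlated at only 0.863 at 4 h and 0.878 at 10 h. A time score was computed for each array, the mean log2 value of probe sets higher at 10 h minus that of probe sets lower at 10 h, chosen from the 6 other groups without the array scored. The array labelled phyB-1 16 °C 4 h replicate 2 scored 1.69, where the other arrays labelled 4 h scored -1.61 to -1.32. The array labelled phyB-1 16 °C 10 h replicate 2 scored -1.27, where the other arrays labelled 10 h scored 1.39 to 1.88. An exchange of time between these 2 arrays would leave differences averaged over both times as they are and would widen the shared spread, so counts are given with all 16 arrays and in the 14-array fit.

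**Figure D1:**
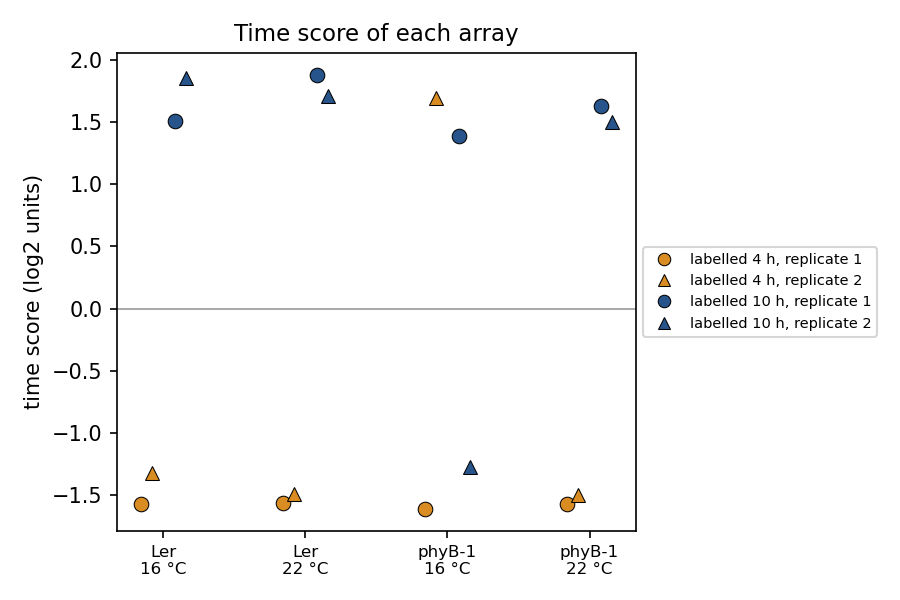
Time score of each array in log2 units (y axis) by genotype and temperature (x axis), with colours for the labelled time and symbols for the replicate. The array labelled phyB-1 16 °C 4 h replicate 2, at 1.69, and the array labelled phyB-1 16 °C 10 h replicate 2, at -1.27, stand with the arrays of the other time.

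At 22 °C, phyB-1 plants had higher levels of 4 transcripts than Ler, and none was called lower (limma, all 16 arrays). Both named ones encode small proteins of the lipid transfer and seed storage protease inhibitor superfamily. AT3G53980 was higher (log2 1.99 ± 0.27 SE, 4 arrays against 4, adjusted p = 0.018). Its intensities were 71.6 ± 16.6 in phyB-1 against 5.84 ± 2.51 in Ler (SD, n = 4). Its log2 change was 0.95 to 2.07 over the 25 alternatives that kept its probe set, which do not include offset 1. AT5G05960 was 2.36-fold higher (log2 1.24 ± 0.18, adjusted p = 0.038), a call lost in 15 of 28 alternatives. The 2 others were unnamed probe sets, given here after their values were seen. 259417_at was 8.24-fold higher (log2 3.04 ± 0.33, adjusted p = 0.0042), at 343 ± 134 against 26.2 ± 9.69, and 254452_at was higher (log2 1.89 ± 0.23, adjusted p = 0.011), at 67 ± 6.58 against 7.43 ± 8.66. The Ler levels of AT3G53980 and 254452_at lie near the lower quartiles of the Ler arrays at 22 °C (5.84 to 10.9), at background, so the offset of 16 sets the size of these 2 log2 values. The next smallest p-values belonged to AT1G35710, a receptor-like kinase gene, AT1G52770 and IAA29, all at adjusted p = 0.15.

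The 14-array fit called 170 probe sets at 22 °C, 101 higher and 69 lower in phyB-1, among them all 4 above. IAA29, an auxin-inducible transcriptional repressor gene of the shade avoidance list, rose by log2 1.30 ± 0.17 (adjusted p = 0.00095), with 1.27 in replicate set 1 and 1.33 in set 2. GH3.5, which encodes an enzyme that conjugates auxin to amino acids, rose by 0.71 ± 0.16 (adjusted p = 0.038). The expansin genes EXPA15 (0.67 ± 0.16) and EXPA8 (0.61 ± 0.14) also rose, at adjusted p = 0.049 and 0.045. Other genes that rose were AT5G20740 (log2 1.28), AT1G58070 (1.24), AT5G58390 (1.05), AT4G16970 (1.02) and AT5G44400 (1.01), with AT5G20740 and AT4G16970 near background in Ler (11.2 and 8.09). The largest falls were in AT1G13470 (log2 -1.75 ± 0.24, adjusted p = 0.0016), AT3G48640 (-1.53), AT5G55450, a lipid transfer protein gene (-1.49), AT3G60420 (-1.37), AT1G35710 (-1.14), AT1G23840 (-1.07, near background in phyB-1 at 10.4) and AT4G11000 (-1.06). DFR, the dihydroflavonol reductase of anthocyanin synthesis, fell by 1.14 ± 0.16 (adjusted p = 0.0017), from 99.6 ± 38.9 in Ler to 34.3 ± 8.54 in phyB-1. COR15A was at log2 0.49 ± 0.12 (adjusted p = 0.051).

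As groups, the 3 shade avoidance genes tested (IAA29, HAT2 and YUC2) were shifted up at 22 °C, with a median log2 change of 0.56 (camera, all 16 arrays, adjusted p = 6e-04). With an estimated correlation the adjusted p was 0.04 for all 16 arrays. In the 14-array fit the shift was called at the preset correlation but not with an estimated one. The 4 auxin response genes were shifted up with a median of 0.56 (adjusted p = 6e-04; adjusted p = 0.071 with an estimated correlation), and IAA29 is in both lists. The 3 flavonoid genes were shifted down with a median of -0.33 (adjusted p = 0.0017; adjusted p = 0.071 with an estimated correlation). No member of these lists was called over all probe sets with all 16 arrays, while 1 shade avoidance, 2 auxin response and 1 flavonoid gene passed when adjusted over the list alone. In the 14-array fit the 8 cell wall expansion genes were also shifted up (adjusted p = 0.0076; adjusted p = 0.26 with an estimated correlation), with 2 called higher over all probe sets and 3 when adjusted over the list alone. The 7 photosynthesis genes were shifted down there (median -0.10, adjusted p = 0.041; adjusted p = 0.28 with an estimated correlation), and none was called over all probe sets. The flowering time genes (adjusted p = 0.71) and the reference genes (median 0.02, adjusted p = 0.79) were not shifted. With offset 1 no probe set was called at 22 °C, though AT3G53980 fell below the filter there and was not tested. The leave-out fits gave 0 to 9 calls. The log2 ratio of GAPDH 3' to 5' control signal, a measure of RNA integrity, was higher in phyB-1 than in Ler in all 4 pairs of arrays at 22 °C (0.596 against 0.399 and 0.812 against 0.474 in set 1, 0.615 against 0.323 and 0.787 against 0.752 in set 2). The actin ratio, the other such measure, was higher in phyB-1 in 3 of the 4 pairs and lower at 4 h in set 2 (3.47 against 3.98), so the 2 measures differ and an effect of RNA integrity is neither shown nor excluded.

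**Figure D2:**
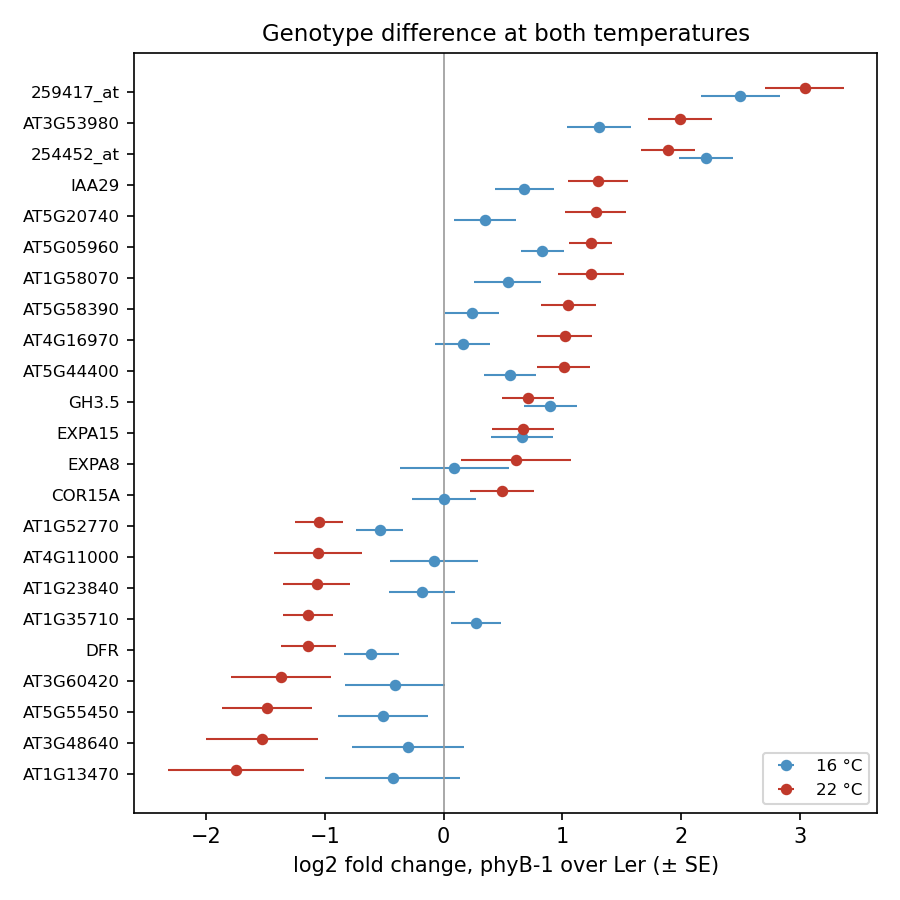
Log2 fold change of phyB-1 over Ler (x axis, mean over both times, bars ± SE, 4 arrays against 4, all 16 arrays fitted) at 16 °C and 22 °C for the genes and probe sets named at 22 °C (y axis). Probe set 259417_at lies at 3.04 at 22 °C and 2.50 at 16 °C, while AT1G35710 lies at -1.14 at 22 °C and 0.27 at 16 °C, a difference that was not called.

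At 16 °C, 2 probe sets were called, both higher in phyB-1 and both unnamed. 254452_at was higher by log2 2.21 ± 0.23 (adjusted p = 0.0037), at 79.5 ± 11.3 against 5.24 ± 6.65 in Ler, and 259417_at by log2 2.50 ± 0.33 (adjusted p = 0.02), at 113 ± 67 against 4.52 ± 4.71 (SD, n = 4). Both Ler levels are at background, below the lower quartiles of the Ler arrays at 16 °C (6.74 to 11.1), so the offset of 16 sets the size of these log2 values, as for AT3G53980 (3.88 ± 2.08 in Ler). The 5 named genes of smallest p missed the threshold. They were LTI30, a cold-induced dehydrin gene (2.30-fold, SE 0.19 log2 units, adjusted p = 0.068), AT5G01870, a lipid transfer protein gene (1.31 ± 0.22, adjusted p = 0.11), AT4G33150 (1.71 ± 0.34, adjusted p = 0.31), AT3G53980 (1.31 ± 0.27, adjusted p = 0.31) and MYC3, a transcription factor gene of the jasmonate pathway (0.85 ± 0.18, adjusted p = 0.31). AT4G33150 was at 0.80 in replicate set 1 and 2.61 in set 2, which holds the disputed arrays. AT5G01870 was at 0.78 and 1.85 in the sets, while MYC3 was alike in them (0.84 and 0.86). COR15A was at 0.00 ± 0.27.

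The 14-array fit called 48 probe sets at 16 °C, 21 higher and 27 lower, with phyB-1 represented by replicate 1 alone. LTI30 rose by 1.09 ± 0.17 (adjusted p = 0.0091), and the difference in LTI30 was 1.11 in replicate set 1 and 1.29 in set 2. LHCB4.3, a minor antenna protein gene of photosystem II, fell by 1.08 ± 0.21 (adjusted p = 0.037), and was lower in both sets. AT5G46780 rose by 1.14 ± 0.23 (1.32 and 1.16 in the sets). Several other calls were carried by set 1. AT3G45310 fell by 1.31 ± 0.16 in this fit but stood at -1.25 in set 1 and -0.19 in set 2, and AT5G41330 at -1.30 and -0.10. ECS1 was called lower in this fit, with -0.92 in set 1 and 0.64 in set 2. One of the 2 arrays behind phyB-1 at 16 °C in this fit, 10 h replicate 1, had the highest log2 ratio of GAPDH 3' to 5' control signal, at 1.63 against 0.812 on the next array of that time. The other, 4 h replicate 1, was the highest at 4 h, at 1.03. The actin ratio does not mark these arrays, and at 3.17 it was the lowest of the 10 h arrays on 10 h replicate 1, so poorer RNA is not established.

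By list, the flavonoid genes were shifted down at 16 °C (median -0.61, adjusted p = 0.01) and the photosynthesis genes down (median -0.10, adjusted p = 0.016), and the auxin response (median 0.40, adjusted p = 0.012) and cold response genes (median 0.28, adjusted p = 0.016) up, with all 16 arrays. None of these held with an estimated correlation (adjusted p = 0.23, 0.32, 0.23 and 0.32), and none was called in the 14-array fit. With all 16 arrays no list member was called over all probe sets, while 2 auxin response, 2 cold response and 1 photosynthesis gene passed when adjusted over the list alone. Shade avoidance genes had a median of 0.16 and were not shifted as a list, with IAA29 (0.68 ± 0.25) the 1 gene that passed over the list alone. The replicate block left 1 of the 2 called probe sets, and the single calls fell to 0 when only the 16 °C arrays were fitted. Quantile normalization and median centring each gave 2 higher and 1 lower call.

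The genotype by temperature interaction asks directly whether the phyB effect differed between temperatures. No probe set was called with all 16 arrays, where 321 had an unadjusted p under 0.05, or in the 14-array fit, where 1155 did (limma). The genes of smallest p, which all missed the threshold at adjusted p = 1, included AT1G35710, with a phyB effect lower at 22 °C than at 16 °C by 1.41 ± 0.30 log2 units, AT5G24460 (-1.15 ± 0.27) and the plastid gene psbA (-0.82 ± 0.20). The smallest adjusted p in the 14-array fit was 0.14, for AT3G45310 (1.25 ± 0.20, with 1.26 in set 1 and 0.05 in set 2) and BCAT4, a gene of methionine chain elongation in glucosinolate synthesis (1.07 ± 0.18, with 1.02 in set 1 and 1.17 in set 2). COR15A was at 0.49 ± 0.39. No list was called for the interaction. The smallest p-values were those of the shade avoidance genes (median 0.58, adjusted p = 0.17) and the cold response genes (median -0.10, adjusted p = 0.18), and the reference genes were at adjusted p = 0.68. For single probe sets, simulated interactions of 1 log2 unit were recovered in 17 of 50 cases, so differences of that size were often not detectable with these arrays.

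Across the 13648 probe sets, the phyB effects at the 2 temperatures correlated at r = 0.27 (Spearman 0.23); the comparisons share no arrays, and probe sets are not independent replicates. Taken between different replicate sets, the correlations were 0.23 and 0.17, and within sets 0.15 and 0.16. For comparison, the phyB effect at the same temperature correlated between the replicate sets at 0.43 at 22 °C and 0.26 at 16 °C. Even a repeat of the same comparison thus did not correlate highly. Both probe sets called at 16 °C were also called at 22 °C, where independent lists would share 0.00059. The 2 comparisons use the same estimate of the spread of each probe set, which can by itself raise the number of shared calls. Of the calls of the 14-array fit, 7 of the 21 higher and 7 of the 27 lower calls at 16 °C were shared with 22 °C, against 0.16 and 0.14 for independent lists.

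Whether loss of phyB in the cool resembles warming of the wild type was examined by setting the phyB effect at 16 °C against the 22 °C minus 16 °C difference in Ler. Their covariance across probe sets was 0.016 (r = 0.23), but both share the Ler 16 °C arrays, and simulated groups without any change gave a covariance of 0.0146 to 0.0327, by which of 4 fits supplied the spread. The observed value lies within that range, so the shared arrays alone can give it. With the Ler arrays split, so that each effect came from a different replicate set, the covariance was -0.00234 and the correlations were 0.04 and -0.07. With all 16 arrays no call was shared. In the 14-array fit 7 higher calls and 1 lower call were shared, against 0.74 and 0.92 for independent lists, a count that takes no account of the shared Ler arrays.

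In Ler, 2 of 7 cold response genes and 1 of 3 flavonoid genes were called lower at 22 °C than at 16 °C. LTI30, of the cold response list, fell by 1.93 ± 0.19 log2 units (4 arrays against 4, adjusted p = 0.00069), from 179 ± 46.1 at 16 °C to 34.6 ± 7.7 at 22 °C (SD, n = 4). COR15B, which encodes a cold-induced chloroplast protein, fell by 1.69 ± 0.27 (adjusted p = 0.02), from 2730 ± 996 to 1040 ± 810, and DFR fell by 1.19 ± 0.23 (adjusted p = 0.042), from 264 ± 145 to 99.6 ± 38.9, a call lost in 16 of 28 alternatives. AT3G09440, a gene of the heat shock cognate 70 family, fell by 1.77 ± 0.22 (adjusted p = 0.0042), and AT3G16670 (-1.53), AT5G01870 (-1.48), AT5G59330 (-1.29) and AT4G35320 (-1.22) fell as well. ROF2, a heat-induced FKBP-type immunophilin gene, rose by 1.27 ± 0.19 (adjusted p = 0.014), from a level near background, 8.18 ± 2.07, to 42.2 ± 6.49. Other genes that rose were AT1G67865 (2.12), AT2G32160 (1.51), RING1 (1.21), AT3G24100 (1.18), AT1G07440 (1.10), AT5G39730 (1.09) and AT2G15580 (1.09), and the call of AT2G32160 was lost in 17 of 28 alternatives.

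In all, 54 probe sets were called between temperatures in Ler, 23 higher and 31 lower at 22 °C. The fit with the replicate block called 86, and the 14-array fit called 946 (479 higher, 467 lower), including all 54. COR15A was at -1.29 ± 0.27 with all 16 arrays (adjusted p = 0.077) and was called in the 14-array fit (adjusted p = 5.6e-06), with -1.06 and -1.52 in the replicate sets, as was COR47, a dehydrin gene (-1.04 ± 0.12, adjusted p = 7e-05). In that fit UGT75C1 (-1.63 ± 0.25, near background at 22 °C at 15.5 ± 18.7) and UF3GT (-0.88 ± 0.15), glycosyltransferase genes of anthocyanin modification, also fell, as did GI, a clock and flowering gene (-0.66 ± 0.14), LHCB4.3 (-0.70 ± 0.16) and XTH16 (-0.66 ± 0.12), while EXPA8 rose (0.56 ± 0.14).

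By list in Ler, the 7 cold response genes were shifted down with a median of -1.04 (camera, adjusted p = 6.6e-05; adjusted p = 0.21 with an estimated correlation). Of these genes, 2 were called lower over all probe sets and 3 when adjusted over the list alone. COR27 (0.31), COR28 (0.33) and ZAT10 (0.24) of this list did not pass. The 3 flavonoid genes were shifted down with a median of -1.19 (adjusted p = 1.4e-05, and 0.043 with an estimated correlation). Of these genes, 1 was called over all probe sets and 3 when adjusted over the list alone. In the 14-array fit the flavonoid shift was called at the preset correlation but not with an estimated one. The flowering time (adjusted p = 0.74), photosynthesis (adjusted p = 0.55) and reference genes (adjusted p = 0.95) were not shifted.

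**Figure D3:**
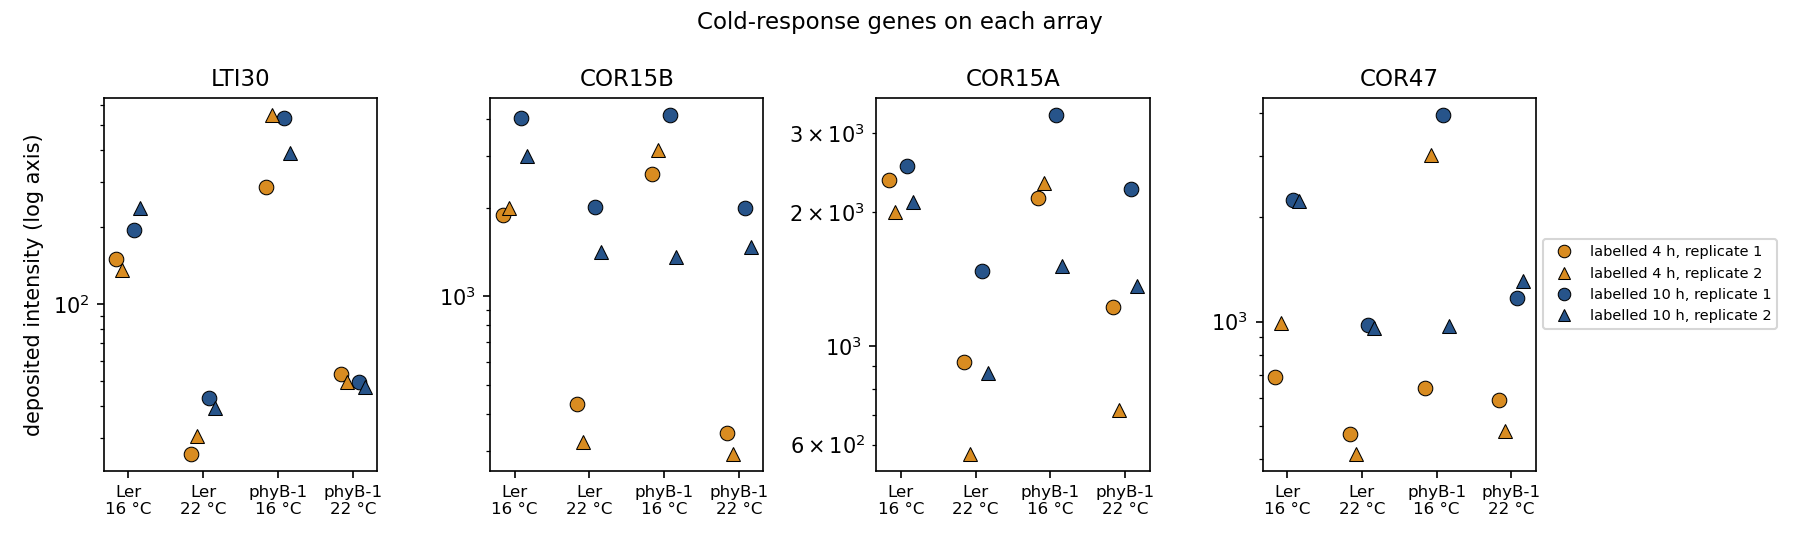
Deposited intensity (y axis, log axis) of LTI30, COR15B, COR15A and COR47 on each of the 16 arrays by genotype and temperature (x axis), with colours for the labelled time and symbols for the replicate. For LTI30 the 4 arrays averaged 179 in Ler and 439 in phyB-1 at 16 °C, and 34.6 and 49.9 at 22 °C.

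In phyB-1, LTI30, COR15B and DFR were lower at 22 °C, as in Ler. LTI30 fell by 2.74 ± 0.19 log2 units (adjusted p = 1.7e-05), from 439 ± 125 to 49.9 ± 2.37 (SD, n = 4), COR15B fell by 1.79 ± 0.27 (adjusted p = 0.0089) and DFR by 1.73 ± 0.23 (adjusted p = 0.003), from 155 ± 50.9 to 34.3 ± 8.54. AT5G01870 (-2.22), AT5G59330 (-1.55), AT3G16670 (-1.21), AT5G24570 (-0.97) and AT3G05730 (-0.80) also fell, with AT5G24570 losing its call in 20 of 28 alternatives. SPCH, the transcription factor gene that starts the stomatal lineage, fell by 1.24 ± 0.17 (adjusted p = 0.0036). ROF2 rose by 1.82 ± 0.19 (adjusted p = 0.00065), from a level near background, 11 ± 4.3, to 84.4 ± 37.8. The other rises were AT1G67865 (2.69 ± 0.33), AT4G19430 (2.23 ± 0.26), AT1G72230 (1.61, lost in 15 of 27 alternatives), AT1G64360 (1.48), AT5G22580 (1.37), AT3G16800 (1.36) and AT3G24100 (1.34). AT4G19430 was at background at 16 °C (3.02 ± 1.89), so the offset sets the size of its rise. The rise was 1.04 to 2.49 over the 26 alternatives that kept its probe set. Offset 1 was not among them, since the probe set fell below the filter there.

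In total 87 probe sets were called in phyB-1, 52 higher and 35 lower at 22 °C, and 790 in the 14-array fit (482 higher, 308 lower), including all 87. Fitting only the phyB-1 arrays left 8. In the 14-array fit phyB-1 at 16 °C is the 2 arrays with the highest GAPDH 3' to 5' ratios (1.03 and 1.63, against 0.596 to 0.812 at 22 °C), while their actin ratios (3.21 and 3.17) lie below those at 22 °C (3.47 to 3.99). In Ler the GAPDH ratio was also higher at 16 °C in 3 of 4 pairs and the actin ratio lower in 3 of 4, so RNA integrity is neither shown nor excluded as a part of the temperature differences. COR15A was at -0.79 ± 0.27 (adjusted p = 0.28) and was called in the 14-array fit (adjusted p = 0.0067), where COR47 (-0.97 ± 0.16), UF3GT (-1.06 ± 0.20) and SMZ, a repressor of flowering (-1.62 ± 0.35), also fell. COR28, also of the cold response list, was at 0.55 ± 0.72 with all 16 arrays. At 4 h it was near background (2.34 at 16 °C in replicate 1, 11.4 and 10.9 at 22 °C). It went the other way from COR47 in the 14-array fit and rose by 0.95 ± 0.26. AGL24, a promoter of flowering, rose there by 0.87 ± 0.21 (adjusted p = 0.021), EXPA8 by 1.25 ± 0.19 (adjusted p = 0.00086) and LHCB4.2 by 0.67 ± 0.15 (adjusted p = 0.015). The fall of SMZ was -1.76 in set 1 and -0.54 in set 2, and -1.15 ± 0.37 with all 16 arrays. SMZ was near background in phyB-1 at 22 °C (13.5 ± 10.3).

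By list in phyB-1, the cold response genes were shifted down with a median of -0.85 (adjusted p = 9.1e-07; adjusted p = 0.095 with an estimated correlation), with 2 called lower over all probe sets and 5 when adjusted over the list alone. The flavonoid genes were shifted down with a median of -0.94 (adjusted p = 3.3e-05; adjusted p = 0.061 with an estimated correlation), with 1 called over all probe sets and 2 when adjusted over the list alone. The photosynthesis, flowering time and reference genes were not shifted (adjusted p = 0.67 for each).

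The temperature effects in the 2 genotypes, which share no arrays, correlated at r = 0.56 across probe sets. Taken between different replicate sets the correlations were 0.27 and 0.34. For comparison, the temperature effect in the same genotype correlated between the sets at 0.32 in Ler and 0.44 in phyB-1. Of the 23 higher calls in Ler, 15 were also called higher in phyB-1, against 0.088 for independent lists, and of the 31 lower calls 17 were shared, against 0.079. Here too the comparisons use the same estimate of the spread, so the lists are not independent. The 14-array fit had 172 higher and 165 lower calls in common, against 17 and 11.

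Between 4 and 10 h, 4 of 7 cold response genes were called higher, and 3 of 7 photosynthesis and 3 of 3 flavonoid genes lower. AKINBETA1, a subunit of the energy-sensing SnRK1 kinase and the only tested gene of the carbon starvation list, rose by 2.15 ± 0.31 log2 units (8 arrays against 8, adjusted p = 0.0017). The largest rises were in AT3G15630 (3.97 ± 0.70), COR27, a cold- and clock-regulated gene (3.90 ± 0.58, adjusted p = 0.0017), AT5G19120 (3.61), AT3G15450 (3.57), AT3G59350 (3.07), AT1G07050 (2.40), AT2G30600 (2.38) and AT5G61590, an ethylene response factor gene (2.37). The largest falls were in AT1G13650 (-3.72 ± 0.60), AT1G73600 (-2.99), AT3G21670, a nitrate transporter family gene (-2.95), AT5G35970 (-2.81), AT3G56290 (-2.37), ARD4 (-2.32), the sucrose transporter gene SWEET13 (-2.27 ± 0.49, adjusted p = 0.0067) and AT5G15950 (-2.26). These changes were larger in the fit without the disputed arrays, which also adds the replicate block. In the 14-array fit COR27 rose by 4.91 ± 0.15, AT3G15450 by 4.42 ± 0.09, AKINBETA1 by 2.69 ± 0.11 and SWEET13 stood at -3.12 ± 0.12. COR27 was at background at 4 h in 3 groups (5.97 and 8.51 in Ler at 16 and 22 °C, 5.9 in phyB-1 at 22 °C), so the offset sets the size of its rise, which ranged from 2.64 to 5.40 over the alternatives. AT5G19120 and AT1G07050 at 4 h and AT1G13650 and AT5G15950 at 10 h were near background in at least 1 group as well. AT3G15630 was also low at 4 h in Ler, with a wide spread (17.5 ± 19 at 16 °C and 19.1 ± 19 at 22 °C, SD, n = 2).

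In total 2613 probe sets were called by time, 1292 higher and 1321 lower at 10 h, and 5415 in the 14-array fit, including all 2613. Of the cold response list 4 genes rose (COR27, COR28 by 2.08 ± 0.51, COR15B by 1.27 ± 0.19 and COR47 by 1.05 ± 0.30), and the list was shifted up with a median of 1.05 (adjusted p = 0.0021; adjusted p = 0.22 with an estimated correlation). Of the photosynthesis list 3 fell, namely LHCB4.2 (-1.32 ± 0.26), PSBY (-0.60 ± 0.12) and RCA, rubisco activase (-0.57 ± 0.14), and the list was shifted down (median -0.31, adjusted p = 0.0049; adjusted p = 0.22 with an estimated correlation). The 3 flavonoid genes fell, UGT75C1 by 1.01 ± 0.31 (near background at 10 h at 22 °C, with the call lost in 14 of 25 alternatives), UF3GT by 0.82 ± 0.18 and DFR by 0.62 ± 0.16 (list adjusted p = 0.012; adjusted p = 0.22 with an estimated correlation). Adjusted over the list alone, 4 cold response, 4 photosynthesis and 3 flavonoid genes passed. COR28 was near background at 4 h in Ler (15.7 and 13.1 at 16 and 22 °C) and in phyB-1 at 22 °C (11.2). UF3GT was near background at 10 h and 22 °C (13.2 in Ler, 13.8 in phyB-1). The offset thus affects the size of both changes, and the rise of COR28 ranged from 1.28 to 2.95 over the alternatives.

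Other called genes by time were SNZ, a repressor of flowering (-1.74 ± 0.31), GI (-0.62 ± 0.15), HYH, a light-signalling transcription factor gene (-1.49 ± 0.45), HAT2 (-0.85 ± 0.18), EXPB1 (-1.22 ± 0.25), EXPB3 (-1.12 ± 0.28) and EXPA15 (-0.82 ± 0.18), which fell, and XTH16 (0.79 ± 0.23), IAA18 (0.76 ± 0.19), the gibberellin receptor gene GID1A (0.66 ± 0.11) and SPT (0.46 ± 0.15), which rose. HYH was at background at 10 h in 3 groups (2.65 to 5.45), and the calls of HYH and SPT were lost in 16 of 25 and 14 of 26 alternatives. The cell wall expansion list had 2 genes called higher and 4 lower and was not shifted as a whole. The flowering time list, with 2 genes called lower (adjusted p = 0.079), and the auxin response list, with 1 called higher (adjusted p = 0.064), narrowly missed. The auxin response list was shifted up in the 14-array fit (adjusted p = 0.049; adjusted p = 0.14 with an estimated correlation) with 4 of 4 genes called higher. With all 16 arrays the reference genes were not shifted (median 0.15, adjusted p = 0.32). The GAPDH 3' to 5' ratio was mostly higher at 10 h (0.752 against 0.323 in Ler at 22 °C, set 2). It was lower in Ler at 16 °C in set 2 (0.531 against 0.631) and between the disputed arrays as labelled. The actin ratio went both ways in Ler at 22 °C (3.34 against 3.26 in set 1, 3.53 against 3.98 in set 2). RNA integrity is neither shown nor excluded as a part of the time differences.

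The genotype by time interaction gave no calls with all 16 arrays (685 at an unadjusted p under 0.05, limma), and 3 in the 14-array fit. These were AT2G05540, a glycine-rich protein gene, whose phyB effect was lower at 10 h by 1.40 log2 units (adjusted p = 0.012), and 2 unnamed probe sets, 245325_at (2.60, adjusted p = 0.011) and 265837_at (-1.68, adjusted p = 0.012), chosen after their values were seen. The temperature by time interaction gave 3 calls, all lower. AT3G09440 differed between temperatures by -0.19 at 4 h and -2.76 at 10 h (interaction -2.57 ± 0.31, adjusted p = 0.019), with 103 ± 40 in Ler at 22 °C and 10 h against 870 ± 150 at 16 °C (SD, n = 2). AT1G62510 differed by 2.88 at 4 h and 0.04 at 10 h (-2.84 ± 0.42, adjusted p = 0.048), and the unnamed 259681_at by 0.70 and -1.29 (-1.99 ± 0.29, adjusted p = 0.048). The fit with the replicate block called 18 and the 14-array fit 412, of which 176 were higher and 236 lower.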

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

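The tests on the disputed arrays' single scores and on replicate 1 were chosen after the time scores were seen; the test of replicate deviations with exchanged times was set before its result was known.

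The 2 disputed arrays stood out among the 8 arrays of their labelled time. The array labelled phyB-1 16 °C 4 h replicate 2 had a time score of 1.69, with the nearest other at -1.32, and the array labelled phyB-1 16 °C 10 h replicate 2 scored -1.27, with the nearest other at 1.39. If the 2 arrays carried each other's time, the replicate deviations of phyB-1 at 16 °C at 4 and 10 h would correlate above 0.1 after an exchange. They correlated at 0.46 exchanged and at -0.43 as labelled, which is consistent with an exchange. A fault of 1 array is argued against by its partner, since both scores, 1.69 and -1.27, lay on the other side. Another timing of phyB-1 plants at 16 °C is argued against by the replicate 1 arrays, which lay outside the range of the other groups by at most 0.29 of its width. Whether plants were sampled at exchanged times or tubes, arrays or labels were exchanged later stays open and was not tested.

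The log2 ratio of GAPDH 3' to 5' control signal on phyB-1 16 °C 10 h replicate 1 was 1.63, far from the next array labelled 10 h at 0.812. The actin ratio of that array, 3.17, was the lowest of the 10 h arrays and did not stand out, so the 2 controls differ. Of 10 such comparisons of array measures 3 stood out in this way, where chance alone marks about 1 in 20.

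The temperature effect differed between times, by the interaction test, for AT3G09440 (-2.57 log2 units), AT1G62510 (-2.84) and the unnamed probe set 259681_at (-1.99).

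Other splits of the same arrays were counted for each comparison, and these counts were chosen as tests after the fits. For the genotypes at 22 °C, 2 of 35 splits of the 8 arrays called at least the real 4 probe sets. The other split was the one by time, with 3074, and every remaining split called 0. A split by time calls many probe sets whatever the genotype or temperature effect. This count therefore could not exclude chance at 22 °C or in Ler, and nothing is concluded from it. For the temperatures in Ler, 2 of 35 splits called at least the real 54, the other being the split by time with 2229, and the rest called 0. At 16 °C, 4 of 35 splits reached the real 2, with up to 2398, and in phyB-1 2 of 35 reached the real 87, with up to 2052. Both high counts came from splits other than the one by labelled time, which called 0 in each, and other than the balanced ones. The arrays in them were not recorded, and chance was not excluded for either comparison. Among the splits that keep both times and both replicate numbers balanced, as the real ones do, the highest counts were 0 at 22 °C, 0 at 16 °C, 0 in Ler and 1 in phyB-1. In the 14-array fit the real counts of 170 at 22 °C and 946 in Ler were each reached by 2 of 35 splits, the real one and the split by time (4733 and 3540), while the highest balanced splits called 1 and 120.

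For time, 2 of 100 assignments of the arrays to the groups called at least the real 2613, the real one among them. The highest other called 2891. An assignment that mixes the times within groups places the large time effect in the residuals, which lowers its count. The count therefore could not exclude chance for time, and nothing is concluded from it. For the interactions the assignments decide nothing, since an assignment can place the large time effect in the residuals or in the interaction itself. The real 3 calls of temperature by time were reached by 2 of 100, with 3 as the highest other. The 0 calls of genotype by temperature and of genotype by time were reached by all 100, with up to 1844 and 158. The 3 calls fell to 0 with median centring and on leaving out any of 9 single arrays (listed with the other leave-out results).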

How the results depend on the processing

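The settings that left out the 2 disputed arrays were added after seeing the data, and the others were set before the data were examined. Direction was kept for all 72 called values of named genes in every alternative that kept the probe set. For genes chosen because their arrays did not overlap between groups, leaving out an array could not reverse the direction. The call was lost for 33 of the 72 under at least 1 alternative, mostly on leaving out an array (218 of 275 losses). Of 18 named values that were not called, COR15A between the genotypes at 16 °C, at 0.00 with all 16 arrays, ranged from -0.28 to 0.28. The other 17 kept their direction wherever their probe sets were tested. The causes of the changes below were not tested unless stated. The replicate block is a fit with the replicate number as a factor. The 3 interactions and the time comparison already use all groups, so no fit of the compared groups alone exists for them.

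Offset 1 gave 0 calls between the genotypes at 22 °C, 1 at 16 °C, 1 for temperature by time and 9 of 48 list shifts against 14. Offset 64 gave 1 at 16 °C. Quantile normalization gave 2 at 22 °C and 6 for temperature by time (2 higher, 4 lower). Median centring gave 27 between temperatures in Ler, 50 in phyB-1 and 0 for temperature by time. Without a filter, where more probe sets are tested, there were 1 at 16 °C, 33 in Ler, 57 in phyB-1 and 1 for temperature by time, and the correlation of the phyB effects was 0.2. With the upper 40% there were 1 at 22 °C, 1 at 16 °C, 6 for temperature by time and 5 list shifts, where fewer list genes are tested. Without the variance trend there was 1 call for temperature by time. The replicate block gave 1 at 16 °C, 86 in Ler and 18 for temperature by time. Array weights gave 40 at 22 °C, 138 in Ler, 45 in phyB-1 and 35 for temperature by time. Fitting only the groups compared gave 93 at 22 °C, 0 at 16 °C, 312 in Ler and 8 in phyB-1. The comparisons at 22 °C and in Ler then lack the disputed arrays, and the other 2 then rest on them more. A 2-fold minimum left 54 in phyB-1 and 707 by time.

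Without the 2 disputed arrays the counts were 69 at 22 °C, 13 at 16 °C, 407 in Ler, 522 in phyB-1, 4488 by time and 139 for temperature by time, and the correlation was 0.21. With the replicate block as well they were 170, 48, 946, 790, 5415 and 412, with 3 for genotype by time. The median residual SD was 0.289 log2 units with all arrays, 0.243 without the 2 and 0.206 with the block.

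Leaving out each array in turn gave 0 to 9 calls at 22 °C, 1 to 20 at 16 °C, 0 to 8 for genotype by temperature, 7 to 90 in Ler, 23 to 211 in phyB-1, 1863 to 3609 by time, 0 to 281 for genotype by time, 0 to 504 for temperature by time and 12 to 18 list shifts. The correlation of the phyB effects ranged from 0.16 to 0.3 and the covariance of the phyB effect at 16 °C with the warmth effect from 0.0114 to 0.0294. Leaving out phyB-1 16 °C 4 h replicate 1, where the group then rests on a disputed array, gave the upper ends 9, 20, 8, 90, 281 and 504. Leaving out the array labelled phyB-1 16 °C 4 h replicate 2 gave 211 in phyB-1 and 3609 by time. The lowest counts in Ler and phyB-1 came without Ler 22 °C 10 h replicate 1 and phyB-1 22 °C 4 h replicate 1. The temperature by time calls fell to 0 without Ler 22 °C 4 h replicate 1 or 2, Ler 22 °C 10 h replicate 1, phyB-1 22 °C 10 h replicate 1 or 2, phyB-1 22 °C 4 h replicate 2, Ler 16 °C 4 h replicate 1, or Ler 16 °C 10 h replicate 1 or 2. A lone array in a group is assumed to vary like the other groups. Probe sets near the offset are limited by their low signal over background.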

Other observations

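The tests in this part were chosen after the results they bear on were seen.

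Among families sharing a symbol stem, the 8 tested ATG genes, which act in autophagy, were shifted up at 10 h with a median of 0.43 log2 units (camera, adjusted p = 0.017 over 29 sets; adjusted p = 0.77 with an estimated correlation), and 4 of them were called higher. ATG8E rose by 1.91 ± 0.38 and ATG8D by 0.85 ± 0.17. Of the 7 tested SWEET sugar transporter genes 4 were called lower at 10 h, and the set was not called (median -0.61, adjusted p = 0.16). The 14-array fit called 5 lower and the set as shifted down (median -0.73, adjusted p = 0.028; adjusted p = 0.70 with an estimated correlation). SWEET17 stood at -0.91 ± 0.22 and SWEET2 at -0.66 ± 0.20 with all 16 arrays. With all 16 arrays, RPL ribosomal protein genes were shifted down at 22 °C in phyB-1 (median -0.28, adjusted p = 0.019; adjusted p = 0.67 with an estimated correlation), and TUB tubulin genes were shifted up in the genotype by temperature interaction (median 0.33, adjusted p = 0.042; adjusted p = 0.59 with an estimated correlation). No family was called between temperatures in Ler. Symbol stems do not part nuclear from chloroplast-encoded genes, so the RPL set can share members with the chloroplast-encoded set below.

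The 68 tested chloroplast-encoded genes were shifted down in phyB-1 at 22 °C, with a median of -0.14 and no single gene called with all 16 arrays (adjusted p = 2.4e-08; adjusted p = 0.46 with an estimated correlation). They were also called for the interaction (median -0.20, adjusted p = 0.00016; adjusted p = 0.59 with an estimated correlation) and between temperatures in phyB-1 (median -0.18, adjusted p = 0.0098; adjusted p = 0.67 with an estimated correlation). If loss of phyB were the cause, both replicate sets would show the shift. Set 2 had medians of 0.00 at 4 h and -0.03 at 10 h, which argues against it. A difference between the replicate sets, with set 1 at -0.40 and -0.26, is consistent with the 4 values. What differed in set 1 stays open.

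In the 14-array fit, which leaves out the 2 disputed arrays and adds the replicate block, more probe sets were called between the genotypes at 22 °C (170) than at 16 °C (48), and without the block the counts were 69 and 13. The larger number of phyB-1 arrays at 22 °C may account for this, but the fit with matched arrays cannot decide it. In that fit the count at 16 °C fell as well, though no further 16 °C array was left out. With phyB-1 also represented by replicate 1 alone at 22 °C, 12 arrays remained, and 13 probe sets were called at 22 °C and 13 at 16 °C. A stronger effect of phyB loss at 22 °C was not excluded: the interaction test called 0 probe sets, and the covariance of the genotype effect between the replicate sets, which share no arrays, was 0.0325 at 22 °C and 0.0239 at 16 °C. For the interaction itself that covariance was 0.0213 (r = 0.15).

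The genotype by temperature difference of BCAT4 was alike in the replicate sets (1.02 and 1.17), though it was not called.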
